A study of Mus musculus with 37 samples.

How the data were processed

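Bone marrow from the femur and spleen of wild-type mice were profiled by RNA sequencing, with 19 marrow and 18 spleen libraries. Per the labels' protocols, RNA was extracted with a NucleoSpin RNA Plus kit, and polyadenylated RNA was made into TruSeq stranded mRNA libraries and sequenced on a NovaSeqXPlus. Per the submitters' processing notes, the tools were kallisto 0.46.1 and sleuth, named without their roles, with the genome build GRCm38. The deposited table gives a signal per gene and library: abundances that the authors had scaled per library, with column totals between 657920 and 2652300. Neither the exact exported quantity nor the scaling is stated in the sources used here, and read counts were not analysed here.

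Gene names, coordinates and biotypes came from GENCODE M21, which held 35629 of the 35885 gene identifiers (99.3%). No pair of columns was identical, the highest correlation between libraries was 0.989, and none of 14 housekeeping genes had a value of 0 in any library. Depth was estimated from the steps between low values in 9751 single-transcript genes longer than 600 bp with an assumed fragment of 200 bp. Of these low values 65.0% to 81.4% lay within 0.1 of a whole read, which gave 3.62 to 35.1 M reads per library. One read equalled a value times length beyond the fragment of 16.2 to 160 by library, with a median of 55.1. A value of 1 is therefore a single read or less only where a gene exceeds the fragment by no more than so many bp. Longer genes hold more reads at this value, and changes near it are least precise for short genes and in shallow libraries. Per library 10926 to 13059 genes had a value of at least 1.

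Libraries were grouped by tissue and treatment as the labels give them, as separate biological replicates, with 2 to 6 per group. Which libraries of the 2 tissues share an animal is not given in the sources used here, so none were paired. Choices of groups, comparisons, tests and the rule for named genes were made before the data were examined. The 5 groups of a tissue shared a linear model on log2(value + 1), fitted with limma 3.58.1 in R 4.3.3 with a trended and robust variance prior. Genes with a value of at least 1 in as many libraries as the smallest group (3 in marrow, 2 in spleen) were tested, 12442 in marrow and 13945 in spleen. Contrasts compared each stressed group with controls, 10 defeats with 1 defeat, and the rested group with 10 defeats. The difference of the stress effect between tissues was tested as an interaction in a model of all 37 libraries on 14513 genes. P values were adjusted by Benjamini and Hochberg within each comparison, with a threshold of 0.05. This unit called for a test of normalized values; the tests planned for read counts were not run.

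A set of 37 gene lists covered cell types of blood and stroma, lipid mediator genes, stress responses and cell processes. Members past the threshold were counted over all genes and, separately, adjusted over the list alone. Lists were tested with camera at its preset correlation of 0.01 and at a correlation estimated from the data, with p values adjusted over all 222 list tests of a tissue. Where the preset and the estimated correlation disagree, the list is reported by its members. A further list test, fry, was also run on these lists, and its results are not reported here.

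Named genes followed a rule: in each comparison, genes past the threshold whose libraries of one group all lay beyond those of the other, with a mean of at least 2 in the higher group, leaving out predicted gene models and immunoglobulin and T cell receptor segments, up to the 10 with the largest rises and the 10 with the largest falls. To these were added up to 4 members with the smallest p of each list with a call, and a fixed set of genes of lipid mediator synthesis, glucocorticoid response, inflammation and proliferation. One of the fixed genes, Ptgs2, was below the filter.

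Settings planned as alternatives were quantile normalization, no filter, a pseudocount of 0.1, a fold change threshold, fits of only the groups compared, leaving out each replicate, and a block for the number shared by libraries of both tissues. Rescaling to equal totals, median-ratio rescaling, removal of the length trend or of the length and GC trend of each library, library weights, and leaving out 5 spleen libraries with steep length slopes were chosen after seeing the data. Values were simulated with 100 genes changed by a log2 fold of 1 and 100 by 2. The test recovered 80% to 91% and 95% to 100% of them in marrow, and 23% to 49% and 71% to 92% in spleen. False calls numbered 4 to 13 over both tissues. The simulated noise was independent between genes, without the trends shared within real libraries, and each gene had the same spread in all groups. What such trends, or spreads that differ between groups, do to false calls and to recovery is therefore not covered. Left out were the comparisons of 4 defeats with 1 or 10, and the lipid measurements named in the series title, which the table does not hold.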

Results

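RNA sequencing of polyadenylated transcripts was used to follow femoral bone marrow and spleen of wild-type mice of the C57BL/6N strain through social defeat stress, a procedure in which a mouse is exposed to an aggressive opponent. Mice were defeated 1, 4 or 10 times, with 1 defeat per day, and a further group rested for 1 week after 10 defeats. Controls were not defeated. The deposited table held 37 libraries and 35885 genes. In bone marrow there were 3 control, 4 once-defeated, 3 4-times-defeated, 5 10-times-defeated and 4 rested libraries; in spleen these groups held 4, 2, 2, 6 and 4. The values were abundances scaled per library by the authors, not read counts, so depth was only estimated: the steps between low values gave 3.62 to 35.1 M reads per library, with a median of 11.6 M. The shallowest library was a spleen after 1 defeat. The series concerns lipid mediators and immune genes under repeated stress, so genes of lipid mediator synthesis were followed in every comparison. All fold changes are log2 differences of value + 1 with their standard errors, which understates changes of low genes.

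After 1 defeat, the limma test called 1 of 12442 genes in bone marrow, the predicted gene Gm27038, which was lower and was named after its value was seen; 535 genes had an unadjusted p under 0.05. No list had a member past the threshold over all genes, and 1 immediate early gene, of the class that responds first to stimulation, was higher when adjusted over the list alone. Camera called 15 of 37 lists with the preset correlation, such as ribosomal protein genes (median 0.18, adjusted p = 9.31e-14) and mature B cell genes (median -0.48, adjusted p = 0.00046), and none with an estimated correlation (adjusted p from 0.635). The mature B cell list averaged 4.05 in library D17 against 4.79 to 5.09 in the other 3 libraries and 5.03 to 5.40 in controls, and its median fold change was -0.22 without D17. That library also stood apart on the first principal component (1.86 against -32.1 to -24.3 in its group). Without library D15, 2 genes were called, and without control C1, C2 or C4 or libraries D16 or D18 none.

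**Figure D1:**
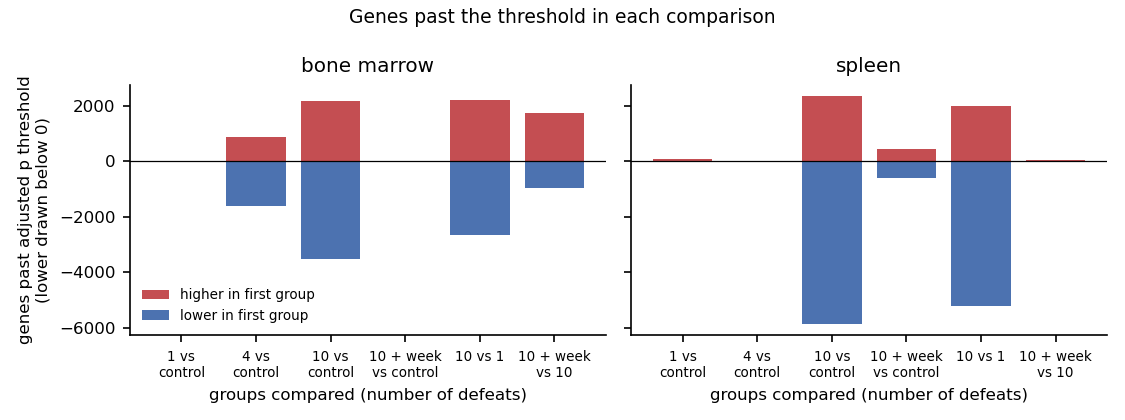
Number of genes past an adjusted p of 0.05 in the limma test for each comparison in bone marrow (left) and spleen (right). Bars above 0 count genes higher in the first group named and bars below 0 count genes lower in it; after 10 defeats 2177 genes were higher and 3517 lower in marrow, and 2348 were higher and 5848 lower in spleen.

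After 4 defeats, bone marrow had lost transcripts of lymphocytes and gained those of granule-forming neutrophil precursors. Of 22 mature B cell genes 19 fell, of 19 B precursor genes 15 fell and of 23 T cell genes 21 fell, against 22, 19 and 22 when adjusted over the list alone. With quantile normalization 12 T cell genes fell, and 16 with median-ratio rescaling. Cd22, a B cell inhibitory receptor, changed by -2.40 ± 0.54 (SE; adjusted p = 0.00898), and Il7r, the interleukin 7 receptor needed by lymphoid progenitors, by -2.26 ± 0.43 (adjusted p = 0.00392). Tcf7, a T cell transcription factor on chromosome 11 (52252371 to 52283014, GRCm38), averaged 7.61 ± 1.42 in controls (SD, n = 3) and 2.06 ± 0.968 after 4 defeats (SD, n = 3). The T cell receptor constant gene Trac changed by -1.73 ± 0.30. All 10 MHC class II genes fell, Ciita, their master regulator, by 1.65 ± 0.36. In addition, 10 of 16 natural killer genes fell and 1 rose (13 and 1 adjusted over the list alone, 6 and 1 with quantile normalization), with Klrd1 at -1.41 ± 0.28. Of 19 tissue macrophage genes 13 fell (16 adjusted over the list alone), with Siglec1 at -1.04 ± 0.22. In the other direction, 13 of 15 early granule genes and 10 of 23 mature neutrophil genes rose (15 and 14 adjusted over the list alone). Mpo, the granule enzyme myeloperoxidase (chromosome 11, 87793581 to 87804413), averaged 603 ± 48.9 in controls and 1458 ± 387 after 4 defeats (SD, n = 3 each). Prtn3, proteinase 3, rose by 1.99 ± 0.27 (adjusted p = 0.00119). Further rises were Stfa2, a stefin protease inhibitor with near-identical family members, at 3.72 ± 0.48, Wfdc17 at 2.58 ± 0.46 and Lrg1 at 2.09 ± 0.37.

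The leukotriene pathway, which turns arachidonic acid into leukotrienes, had 5 of 15 genes higher and none lower after 4 defeats in marrow by limma (5 and 0 adjusted over the list alone). Alox5ap, the protein that presents arachidonic acid to 5-lipoxygenase, rose by 1.18 ± 0.24 (adjusted p = 0.00542), 5-lipoxygenase itself, Alox5, by 0.66 ± 0.19 and Lta4h, which makes leukotriene B4, by 0.87 ± 0.23. Ggt1, a gamma-glutamyltransferase that trims cysteinyl leukotrienes, rose by 3.25 ± 0.56 and the leukotriene B4 receptor Ltb4r1 by 1.00 ± 0.22. Hpgds, a prostaglandin D synthase, fell by 1.00 ± 0.20 and the sphingosine phosphate receptor S1pr1 by 1.66 ± 0.29. Ptgs1 (0.39 ± 0.18), Ltc4s (-0.11 ± 0.19), Alox12 (-1.04 ± 0.46) and Alox15 (-0.37 ± 0.38) did not pass the test. Early granule and mature neutrophil genes rose in the same libraries, with list medians of 1.10 and 0.66. In whole marrow a change of these lipid genes per cell cannot be told from a change in the share of cells. In total 880 genes rose and 1613 fell. The mean haemoglobin share of the values was 24.7% ± 13.3 (SD, n = 3) against 42.1% ± 2.96 in controls (SD, n = 3). Camera with a preset correlation called these lists (adjusted p = 1.47e-12 to 0.0411). No call held with an estimated correlation (adjusted p = 0.635). Quantile normalization gave 1127 higher and 837 lower genes and median-ratio rescaling 1500 and 1021, so the direction of the majority depends on scaling. The total was 1153 without control C2, 804 without C4, 1283 without library D14 and 684 without D12, where Alox5, Lta4h and Cd22 lost their calls at 0.45, 0.66 and -1.76. Alox5 also lost its call without C1 or C4 (0.62, 0.63) and Lta4h without C4 or D14 (0.86, 0.84).

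After 10 defeats the same tissue showed fewer B cell, T cell and erythroid transcripts and more neutrophil and monocyte transcripts. All 19 B precursor genes and 21 of 22 mature B cell genes fell, with list medians of -2.30 and -2.34. Cd79a, a B cell receptor component on chromosome 7 (24897381 to 24902197), averaged 268 ± 60.6 in controls (SD, n = 3) and 39.7 ± 24.5 after 10 defeats (SD, n = 5). Ms4a1 and Vpreb3, a surrogate light chain partner of pre-B cells, changed by -2.89 ± 0.52 and -2.88 ± 0.74. Ighd, the IgD constant gene, changed by -3.34 ± 0.76. In all 71 of 203 immunoglobulin segments fell. Of 23 T cell genes 20 fell (Il7r -2.36 ± 0.38, Cd8b1 -1.41 ± 0.21), as did 8 of 10 MHC class II genes (Ciita -1.65 ± 0.32) and 13 of 15 dendritic cell genes. With quantile normalization 13 T cell and 8 dendritic cell genes fell. Of 27 erythroid genes 22 fell (24 adjusted over the list alone), among them the carbonic anhydrase Car1 at -1.62 ± 0.31. The haemoglobin share was 21.3% ± 6.60 (SD, n = 5). Mature neutrophil genes rose in 22 of 23 cases and early granule genes in 14 of 15. S100a9, a calcium-binding protein abundant in neutrophils (chromosome 3, 90692632 to 90695721), averaged 25026 ± 2270 in controls and 80017 ± 24211 after 10 defeats (SD, n = 3 and 5). S100a8 rose by 1.44 ± 0.27 (1.08 and not called with quantile normalization), Camp by 1.41 ± 0.20, Prtn3 by 1.76 ± 0.24 and Lrg1 by 2.31 ± 0.33. Of 20 monocyte genes 14 rose and 1 fell (15 and 1 adjusted over the list alone, 9 and 1 with totals made equal), with the chemokine receptor Ccr2 at 1.39 ± 0.22 and Ly6c2 at 1.15 ± 0.20.

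Single genes with large rises after 10 defeats in marrow included Fos, an immediate early transcription factor (chromosome 12, 85473890 to 85477273), which averaged 2.49 ± 0.398 in controls (SD, n = 3) and 40.7 ± 16.9 after 10 defeats (SD, n = 5). Its partner Junb rose by 1.59 ± 0.23, and 10 of 19 immediate early genes rose and 3 fell. Wfdc17 rose by 3.27 ± 0.41, the chemokine-like Prok2 by 3.09 ± 0.63, the proteoglycan Vcan by 2.81 ± 0.35, the endothelial lipase Lipg by 2.79 ± 0.79, the cytokine Osm by 1.95 ± 0.24 and Il1b by 1.72 ± 0.49, which was not called in a fit of these groups alone. Of 22 genes each, 14 S phase and 12 G2/M genes fell, but 7 and 4 did with median-ratio rescaling. Mki67, a proliferation marker, was at -0.49 ± 0.14 and lost its call without control C4 (-0.40). The glucocorticoid-induced genes Fkbp5 (-0.24 ± 0.25, adjusted p = 0.437) and Tsc22d3 (0.01 ± 0.25, adjusted p = 0.965) did not pass the test. Of the 21 glucocorticoid response genes 5 rose and 8 fell (5 fell with quantile normalization). Ribosomal protein genes rose in 13 of 31 cases and mitochondrially encoded genes in 9 of 13, but with quantile normalization 12 and 1 of them fell and none rose. In total 2177 genes rose and 3517 fell. Camera called the B, T, dendritic, MHC class II, erythroid, neutrophil and monocyte lists with the preset correlation (adjusted p = 1.99e-13 to 0.00141) and none with an estimated correlation (adjusted p = 0.635 to 0.66). The median over all genes was -0.13, and with quantile normalization 2763 genes rose and 2298 fell, and with median-ratio rescaling 2996 and 2409. Leaving out control C4 left 3780 calls.

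**Figure D2:**
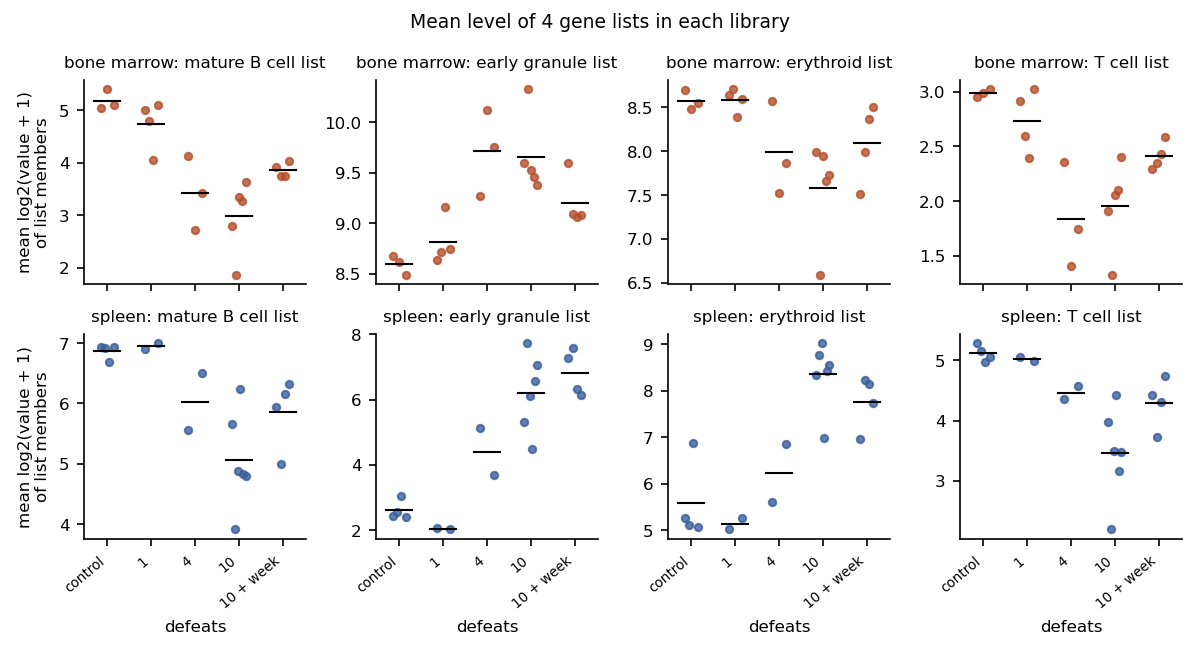
Mean log2(value + 1) of the members of 4 gene lists in each library (points) and group mean (lines) of bone marrow (top) and spleen (bottom), by number of defeats; 10 + week marks the rested group. The mature B cell and T cell lists lay lower after 10 defeats than in controls in both tissues, whereas the erythroid list lay lower in marrow and higher in spleen.

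Lipid mediator genes changed in both directions in marrow after 10 defeats. Mature neutrophil genes rose in the same libraries (list median 1.28). Whole-marrow values do not separate a change per cell from a change in the share of cells. Alox5ap (chromosome 5, 149264767 to 149288153) averaged 466 ± 29.4 in controls (SD, n = 3), 1077 ± 279 after 4 defeats (SD, n = 3) and 1391 ± 365 after 10 (SD, n = 5), with adjusted p = 0.000138 for the last against controls. Alox5 (chromosome 6, 116410077 to 116461178) averaged 60.6 ± 4.94 and 103 ± 14.4 in controls and after 10 defeats. Lta4h rose by 1.01 ± 0.21 and Ggt1 by 2.64 ± 0.50, and in all 7 of 15 leukotriene and lipoxygenase genes rose and 4 fell. Alox15, which oxygenates polyunsaturated fatty acids, changed by -1.23 ± 0.34 (adjusted p = 0.00816) and Hpgds by -0.78 ± 0.18. Ptgs1 (0.24 ± 0.16), Ltc4s (-0.22 ± 0.17) and the platelet lipoxygenase Alox12 (-1.03 ± 0.41, adjusted p = 0.0503) did not pass. Of 31 lipid mediator receptors 10 rose and 8 fell: the formyl peptide and lipoxin receptor Fpr2 rose by 1.15 ± 0.20 and S1pr1 fell by 2.11 ± 0.26. Of 24 genes of polyunsaturated fatty acid synthesis and remodelling 12 fell and 6 rose (10 and 2 with totals made equal), with the stearoyl-CoA desaturase Scd1 at -2.82 ± 0.41. The epoxide hydrolase Ephx1 was at -1.78 ± 0.22. The leukotriene list was not called by camera (adjusted p = 0.0529, and 0.635 with an estimated correlation).

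**Figure D3:**
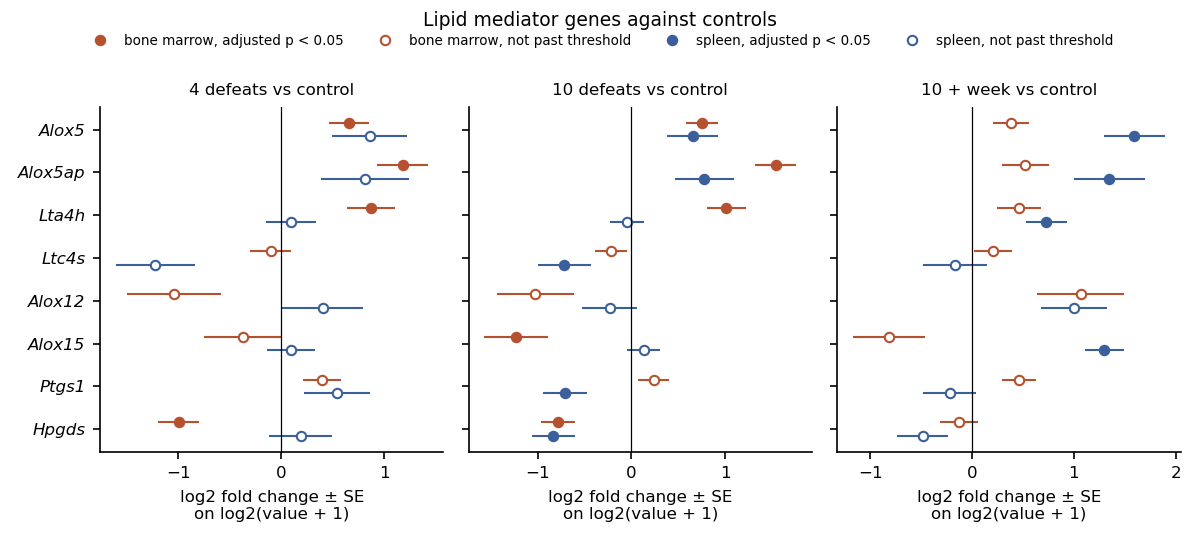
Log2 fold change with its standard error (bars) of 8 genes of lipid mediator synthesis against controls after 4 defeats, 10 defeats and 10 defeats with a week of rest, in bone marrow (brown) and spleen (blue). Filled points passed an adjusted p of 0.05; Alox5ap in marrow was at 1.18 after 4 defeats, 1.54 after 10 and 0.53 after rest, where it did not pass.

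Directly against 1 defeat, 10 defeats gave 2189 higher and 2649 lower genes in marrow. Vcan (2.99 ± 0.33), Wfdc17 (3.28 ± 0.38), the acute phase gene Saa3 (3.43 ± 0.82), Alox5ap (1.41 ± 0.20) and S100a9 (1.29 ± 0.23) were higher, and Cd79a (-2.75 ± 0.60) and Vpreb3 (-2.78 ± 0.68) were lower. Median-ratio rescaling gave 2640 higher and 2158 lower genes.

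After the week of rest no gene in marrow passed the limma test against controls, with 1768 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0723. The rested libraries differed among themselves: D1 and D2 held 16.1% and 21.7% haemoglobin and D3 and D8 36.3% and 39.1% (mean 28.3% ± 11.2, SD, n = 4), with values of -30.9, -28.4, -3.60 and 6.36 on the second principal component. Adjusted over the list alone, 20 of 22 mature B cell genes were lower, with a median of -1.39, and 16 of 22 megakaryocyte genes were higher, with a median of 0.91. Camera gave adjusted p = 2.64e-17 and 5.11e-13, or 0.635 for both with an estimated correlation. Alox5ap was at 0.53 ± 0.23, Alox5 at 0.38 ± 0.18, S100a9 at 0.71 ± 0.26 and Il1b at 1.17 ± 0.51, none past the threshold. Quantile normalization gave 24 higher and 47 lower genes, a fit of these groups alone 104 and 292, and library weights 1050 and 1481.

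Against the 10-times-defeated group, rested marrow had more megakaryocyte, endothelial and B precursor transcripts. Of 22 megakaryocyte and platelet genes 19 rose (21 adjusted over the list alone), with a median of 1.64. The platelet receptor gene Gp1ba (chromosome 11, 70639122 to 70642036) averaged 2.68 ± 1.46 after 10 defeats (SD, n = 5) and 14.7 ± 4.46 after rest (SD, n = 4). Tubb1, Ppbp and Itgb3 rose by 2.42 ± 0.44, 2.31 ± 0.51 and 1.43 ± 0.20. Alox12, expressed in platelets, rose by 2.09 ± 0.38 (adjusted p = 0.00257). Of 15 endothelial genes 13 rose, 14 adjusted over the list alone (Tie1 0.95 ± 0.12, Stab2 1.11 ± 0.18). Of 19 B precursor genes 14 rose, 19 adjusted over the list alone (Bach2 1.58 ± 0.34, Cecr2 1.65 ± 0.37, Sox4 1.03 ± 0.20). Of 22 mature B cell genes 5 rose over all genes and over the list alone, 3 with quantile normalization and 8 with totals made equal, with a median of 0.87 against 1.39 for the precursors; the difference between the lists was not tested. Fos averaged 3.77 ± 1.40 after rest (SD, n = 4), a change of -3.03 ± 0.46 from 10 defeats. Saa3, Prok2, Vcan, Osm and Ccr2 changed by -3.24 ± 0.82, -2.45 ± 0.58, -2.27 ± 0.33, -1.60 ± 0.22 and -1.01 ± 0.20. Of 20 monocyte genes 10 fell and 2 rose, or 4 and 4 with totals made equal. Of 23 mature neutrophil genes 13 fell, 19 adjusted over the list alone, 4 with totals made equal and 6 with quantile normalization, where S100a9 lost its call (-0.50 against -0.92). Alox5ap fell by 1.02 ± 0.20, Ggt1 by 1.96 ± 0.46, and Hpgds rose by 0.65 ± 0.16, without a call when rested D2 was left out (0.55). In all 1716 genes rose and 984 fell. The camera calls of these lists (adjusted p = 1.06e-11 to 0.00412) were lost with an estimated correlation (adjusted p = 0.635 to 0.666). Quantile normalization gave 867 higher and 1096 lower genes, median-ratio rescaling 1151 and 1495 and rescaling to equal totals 3057 and 209. Leaving out library D6 left 1576 calls, rested D3 1660 and rested D2 1301.

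In spleen 1 defeat gave 87 higher and 9 lower genes, 43 of the 96 being annotated pseudogenes. The largest changes were in near-identical copies of abundant genes. Rpl38-ps2 averaged 302 ± 74.4 (SD, n = 2) and was listed at 0 in controls. The histone copy H3f3c rose by 7.06 ± 0.18, Ubb-ps by 4.84 ± 0.31, and Fam177a2 by 2.63 ± 0.36 while Fam177a changed by -2.06 ± 0.32. Their values may depend on how reads shared between such copies were split, which the tests here could not decide. Dusp1, a phosphatase induced by stress and glucocorticoids, rose by 1.85 ± 0.34 (adjusted p = 0.0167), losing its call without library D16 (1.43). S100a9 (-1.28 ± 1.45) and Alox5ap (-0.49 ± 0.43) did not pass. The libraries of this group had slopes of -0.567 and -0.560 in log2 value per 10 points of GC content against -0.207 to 0.176 in controls. Pseudogenes held 12.05% and 15.8% of their values against 6.87% ± 2.56 in controls (SD, n = 4), and haemoglobin 2.0% ± 0.263 (SD, n = 2) against 14.5% ± 5.78 (SD, n = 4). Without the length and GC trend of each library 28 genes were called, 25 of them among the 96. A pseudocount of 0.1 left 27 calls and median-ratio rescaling 37. Without the 5 spleen libraries of steep length slope, all from groups with 10 defeats, 1175 genes were higher and 578 lower, the 96 among them. Quantile normalization gave 207 higher and 112 lower genes, 325 genes were called without library D15 and 56 without control C3.

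After 4 defeats, with 2 spleen libraries, 6 genes rose and none fell, with limma: Lcn2 (4.38 ± 0.73), Mmp8 (4.12 ± 0.63), Hdc (2.08 ± 0.30), Mrgpra2b (1.91 ± 0.25), Phlda2 (1.61 ± 0.22) and Dhrs9 (1.41 ± 0.23). Lcn2 and Mmp8 encode neutrophil granule proteins. Lcn2 (chromosome 2, 32384633 to 32388252) averaged 9.59 ± 4.29 in controls (SD, n = 4) and 306 ± 319 after 4 defeats (SD, n = 2). Adjusted over the list alone, 14 of 22 mature neutrophil, 11 of 22 G2/M and 10 of 22 S phase genes were higher and 10 of 19 natural killer genes lower. Camera called each with the preset correlation (adjusted p = 2.88e-20 to 3.69e-11), and with an estimated correlation gave adjusted p = 0.263, 0.401, 0.344 and 0.263. Without the 5 libraries of steep length slope described below, 148 genes were higher and 97 lower, these 6 among them. In that setting 12 mature neutrophil genes were higher and 8 natural killer, 6 of 10 MHC class II and 3 of 28 T cell genes lower. Library weights gave 191 higher and 141 lower. No gene was called with median-ratio rescaling, and none of these 6 without library D13. In all 195 genes were called without D14, 19 without control C3, 3 without C4 and 2 without C1 or C2.

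**Figure D4:**
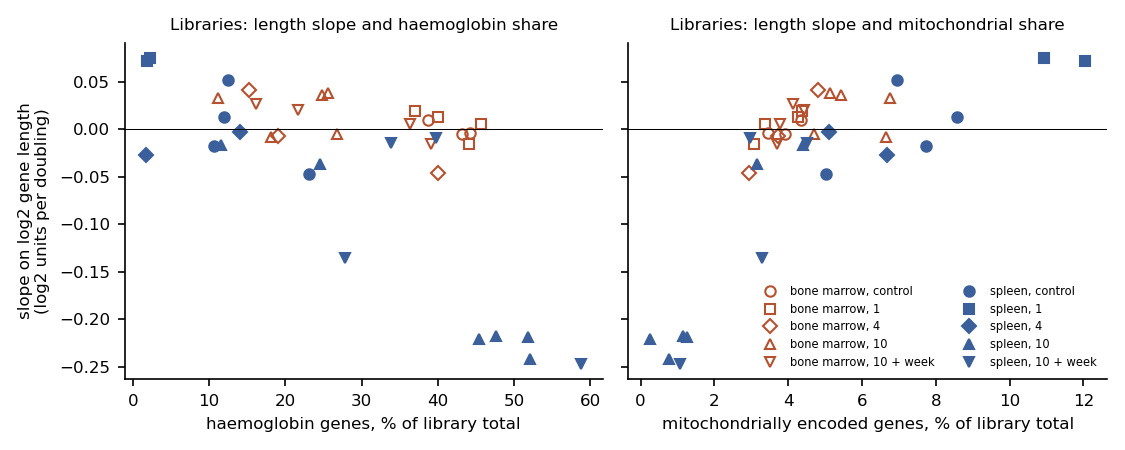
Slope of each library's log2 values on log2 gene length, relative to controls of its tissue, against the share of the library's total held by haemoglobin genes (left) and mitochondrially encoded genes (right), in percent. The 5 spleen libraries with slopes from -0.25 to -0.22 held 45.4% to 58.8% haemoglobin and at most 1.26% mitochondrial values.

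After 10 defeats the spleen gained transcripts of erythroid precursors, of neutrophil precursors and of dividing cells and lost those of T and B cells. List counts below were within 1 when adjusted over the list alone. Of 27 erythroid genes 26 rose, with a median of 2.95. Gata1, the erythroid transcription factor (chromosome X, 7959260 to 7978071), averaged 8.20 ± 5.46 in controls (SD, n = 4) and 72.6 ± 20.2 after 10 defeats (SD, n = 6). Tal1, Rhag and the erythropoietin receptor Epor rose by 3.88 ± 0.42, 3.65 ± 0.43 and 3.05 ± 0.34. Of 15 early granule genes 12 rose. Neutrophil elastase, Elane (chromosome 10, 79886247 to 79888215), averaged 1.71 ± 0.675 in controls (SD, n = 4) and 133 ± 96 after 10 defeats (SD, n = 6). Camp, Prtn3, Ms4a3, Ngp and Mpo rose by 5.80 ± 1.08, 5.60 ± 0.61, 5.56 ± 0.91, 4.64 ± 0.64 and 4.20 ± 0.42. Of 22 mature neutrophil genes 14 rose and 1 fell (7 and 1 without the 5 steep libraries described below), with S100a9 at 5.54 ± 1.08 and S100a8 at 5.10 ± 1.04. Of 22 genes each, 19 S phase and 16 G2/M genes rose (7 S phase genes with totals made equal), among them Rrm2 (2.46 ± 0.31), Cdc6 (1.90 ± 0.24) and the cyclin Ccnb1 (2.43 ± 0.29). Mki67, a long gene, did not pass (0.29 ± 0.34) unless the length trend was removed (1.12).

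T cell genes fell in 26 of 28 cases in the same spleens, mature B cell genes in 20 of 22, dendritic genes in 14 of 17 (7 with quantile normalization, 8 without the steep libraries below) and MHC class II genes in 10 of 10. Bcl11b, a T lineage transcription factor (chromosome 12, 107910403 to 108003602), averaged 5.54 ± 1.11 in controls (SD, n = 4) and 0.842 ± 1.01 after 10 defeats (SD, n = 6). Cd27 changed by -1.48 ± 0.20, the B lineage regulators Pax5 and Bach2 by -3.53 ± 0.55 and -2.49 ± 0.41, and the integrin Itgax by -2.47 ± 0.39. Of the antigen receptor segments, 79 of 168 T cell receptor and 86 of 218 immunoglobulin segments fell. Of 13 mitochondrially encoded genes 12 fell (mt-Nd4 -3.20 ± 0.65), as did 15 of 17 stromal (8 without the steep libraries below) and 15 of 17 endothelial genes. The long cytoskeletal genes Myh9 and Sptan1 changed by -3.11 ± 0.64 and -2.97 ± 0.43, though no list of such genes was tested. Of the 6 libraries, D6, D7, D9 and D10 carried steep length slopes, with mitochondrial shares of 0.257% to 1.26% against 7.07% ± 1.51 in controls (SD, n = 4) and haemoglobin shares from 45.4% upward. Without these and rested library D2, 1172 genes were higher and 2071 lower in place of 2348 and 5848. Of the list members called above, 18 erythroid, 11 early granule, 19 S phase, 23 T cell, 9 mature B cell, 3 MHC class II, 5 endothelial and 10 mitochondrially encoded genes kept their calls in that setting. Some changes were smaller there, though called: Camp 2.86, Ms4a3 2.98, S100a9 2.63, S100a8 2.31, Pax5 -2.11, Bach2 -1.56, Bcl11b -1.06, Itgax -1.55, mt-Nd4 -1.83 and Myh9 -1.24. The median over all genes was -0.36. Quantile normalization gave 3275 higher and 3764 lower genes, median-ratio rescaling 3930 and 3448, and rescaling to equal totals 794 and 7334. Camera calls of these lists (adjusted p = 4.84e-17 to 0.0154) did not hold with an estimated correlation (adjusted p = 0.348 to 0.729).

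Among lipid mediator genes of spleen after 10 defeats, Alox5 (0.65 ± 0.27, adjusted p = 0.0493) and Alox5ap (0.78 ± 0.32, adjusted p = 0.0451) rose and Ptgs1 (-0.71 ± 0.24), Ltc4s (-0.72 ± 0.29) and Hpgds (-0.83 ± 0.23) fell. Each of these lost its call without the libraries of steep length slope, at 0.36, 0.12, -0.60, -0.61 and -0.70. Alox5 lost it without any of C1 to C4, D6, D7 and D10 (0.53 to 0.74), Alox5ap without C1, C2, C4, D6, D7, D9 or D10 (0.62 to 0.80) and Ltc4s without C2, C3, C4, D5, D6 or D9 (-0.76 to -0.54). Lta4h (-0.04 ± 0.18), Alox12 (-0.23 ± 0.29) and Alox15 (0.13 ± 0.17) did not pass. Cell type lists changed in the same spleens, so a change per cell cannot be told from a change in the share of cells. The prostaglandin transporter Slco2a1 (-2.32 ± 0.42), the fatty acid receptor Ffar1 (-1.90 ± 0.27) and Ephx1 (-1.92 ± 0.41) fell and the glutathione transferase Mgst3 rose by 3.91 ± 0.59. Without the steep libraries Slco2a1 and Ephx1 were at -1.31 and -0.87 and called. In all 22 of 32 lipid mediator receptors fell and 3 rose, 7 and 0 without the steep libraries, and 12 fell with the length and GC trend removed. Fkbp5 and Tsc22d3 changed by -2.02 ± 0.50 and -1.27 ± 0.35 and Il1b by 1.64 ± 0.42. Without those libraries they were at -1.09, -0.52 and 0.91 and not called. Compared with 1 defeat rather than controls, 10 defeats gave 1980 higher and 5219 lower genes, with S100a9 at 6.83 ± 1.36 and Alox5ap at 1.27 ± 0.40, the latter not called without D15 (1.22) or D16 (1.32). Without the steep libraries these were at 3.91 and 0.61, the latter not called. The total was 3731 without once-defeated library D16 and 4676 without D15. Quantile normalization gave 2939 higher and 3165 lower genes and median-ratio rescaling 3418 and 2726.

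In rested spleens the neutrophil, erythroid, megakaryocyte and eosinophil transcripts stood above those of controls, with 421 genes higher and 591 lower. Early granule genes rose in 12 of 15 cases with a median of 4.89, mature neutrophil genes in 12 of 22, erythroid genes in 18 of 27 and megakaryocyte genes in 15 of 22, against 12, 16, 26 and 17 adjusted over the list alone. With totals made equal, 11 erythroid and 3 megakaryocyte genes rose. The cathelicidin gene Camp (chromosome 9, 109847379 to 109849617) averaged 12.8 ± 9.39 in controls and 2709 ± 3803 after rest (SD, n = 4 each). Ngp, Lcn2, Elane and Ly6g rose by 6.40 ± 0.70, 5.48 ± 0.60, 5.34 ± 0.59 and 4.34 ± 0.63. S100a8 and S100a9 were at 5.56 ± 1.14 and 5.86 ± 1.18, Tal1 and Rhag at 2.66 ± 0.46 and 2.66 ± 0.48, and the platelet genes Gp9, Ppbp and Treml1 at 2.16 ± 0.31, 2.15 ± 0.33 and 1.79 ± 0.26. Of 18 eosinophil, basophil and mast cell genes 8 rose. Ear1, an eosinophil ribonuclease with near-identical copies (chromosome 14, 43818765 to 43875517), averaged 0.662 ± 0.395 in controls (SD, n = 4), 5.70 ± 3.27 after 10 defeats (SD, n = 6) and 53.1 ± 31.6 after rest (SD, n = 4). The eosinophil peroxidase Epx rose by 2.42 ± 0.26. Of 22 genes each, 12 G2/M and 4 S phase genes rose, or 13 and 13 adjusted over the list alone, and 2 and 0 with totals made equal. Lymphocyte lists lay lower: mature B cell genes averaged at most 6.33 in rested libraries and at least 6.68 in controls, and T cell genes 3.72 to 4.74 against 4.96 to 5.28, with medians of -0.98 and -0.81. Of these 2 of 22 and 2 of 28 genes were called, and 6 and 13 without the steep libraries. Long genes such as Kmt2d (-2.13 ± 0.28) and Dync1h1 (-2.11 ± 0.31) were among the falls. Pax5 changed by -2.62 ± 0.60, losing its call without rested library D2 (-2.14) or control C1, C2 or C4 (-2.52, -2.46, -2.68).

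Leukotriene and lipoxygenase genes rose in 5 of 13 cases in rested spleens (6 adjusted over the list alone, 3 with totals made equal) and none fell. Neutrophil and eosinophil genes rose in the same spleens, so a change per cell cannot be told from a change in the share of cells. Alox15 (chromosome 11, 70344152 to 70352031) averaged 0.331 ± 0.175 in controls (SD, n = 4), 0.456 ± 0.164 after 10 defeats (SD, n = 6) and 2.35 ± 0.989 after rest (SD, n = 4), with adjusted p = 0.00169 for rest against controls. Alox5 rose by 1.60 ± 0.30 and Ltb4r1 by 2.56 ± 0.45, and Ffar1 fell by 1.69 ± 0.30. Alox5ap (1.35 ± 0.35) and Lta4h (0.73 ± 0.20) passed at adjusted p = 0.0319 and 0.0385 and lost their calls without any of C1, C2, C4, D1 and D2, at 1.16 to 1.33 and 0.54 to 0.76, Lta4h also without C3 (0.73). Camera called the leukotriene list with the preset correlation (adjusted p = 0.000145) and not with an estimated correlation (adjusted p = 0.263). The other rising lists (adjusted p = 1.8e-22 to 4.31e-10) had adjusted p = 0.263 to 0.423 with an estimated correlation. The median over all genes was -0.19, quantile normalization gave 735 higher and 626 lower genes, median-ratio rescaling 435 and 301 and rescaling to equal totals 132 and 311. The total was 201 without control C2, 204 without C4, 270 without C1, 241 without library D2 and 481 without D1. D2 held 58.8% haemoglobin and 1.07% mitochondrial values with a length slope of -0.247, and D1 had a slope of -0.135. Without the 5 steep libraries, D2 among them, 752 genes were higher and 1508 lower, with 918 of the 1012 still called. Library weights gave 1422 higher and 3005 lower. Directly against 10 defeats, 38 genes rose and 41 fell. Ear1 (3.02 ± 0.37), Epx (1.52 ± 0.24) and Alox15 (1.17 ± 0.17) were higher and the asparagine synthetase Asns lower (-1.93 ± 0.27). Alox15 lost its call without D7 (1.17) or rested D3 (1.16), as did Epx (1.44 without D3). Without the steep libraries Alox15 (0.91) and Asns (-1.37) were not called. That count went from 2 without 10-times-defeated library D7 to 2316 without D4, and was 10 without D5, 14 without D6, 21 without D9, 27 without D10, 6 without rested D1 or D8 and 2 without rested D3. A fit of these groups alone called none. Quantile normalization gave 17 higher and 30 lower genes, median-ratio rescaling 10 and 25 and rescaling to equal totals 4 and 1.

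The change after 10 defeats differed between spleen and marrow for 6249 of 14513 genes, with the spleen change above the marrow change for 2330 and below it for 3919. S100a9 changed by 3.91 ± 1.21 more in spleen (adjusted p = 0.0106) and Prtn3 by 3.84 ± 0.71 more, whereas the difference for Lta4h was -1.06 ± 0.28 (adjusted p = 0.00326), and that for Alox15 1.36 ± 0.38. For Alox5 the difference was -0.10 ± 0.34 and for Alox5ap -0.76 ± 0.41, neither past the threshold. After rest the difference was called for 529 genes, with S100a9 at 5.15 ± 1.29 (adjusted p = 0.0236) and Alox5 at 1.21 ± 0.36 (adjusted p = 0.0555). Without the steep spleen libraries the differences after 10 defeats were 0.99 ± 0.58 for S100a9 (adjusted p = 0.202, not called), 2.21 ± 0.57 for Prtn3, -0.94 ± 0.28 for Lta4h, 1.44 ± 0.45 for Alox15 and -1.42 ± 0.38 for Alox5ap, the last then called. After rest S100a9 was at 4.30 ± 0.56 and Alox5 at 0.96 ± 0.29, both called. The median difference after 10 defeats was -0.22, and quantile normalization gave 2751 genes above and 3414 below. After rest the total of 529 went from 156 without marrow control C1 to 851 without rested spleen library D3.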

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

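Among 62 sets of values from groups of 4 to 6 libraries, 6 held a library far from the others of its group, where about 1 in 20 is expected by chance. Alox5ap was 872 in rested marrow library D1 against 597 to 626 in the other libraries of that group. Elane was 2.72 in spleen control C3 against 1.30 to 1.43, and the same library held 23.1% haemoglobin against 10.6% to 12.5%. Alox15 was 0.137 in spleen library D6 after 10 defeats against 0.463 to 0.594, and Camp was 8368 in rested spleen library D2 against 382 to 1500. The estimated depth of marrow library D5 after 10 defeats was 20.2 M reads against 6.55 to 10.5 M. No cause was tested for these single libraries.

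The change after 10 defeats differed between tissues by the interaction test for 6249 genes. Spleen minus marrow differences were 3.84 for Prtn3, 4.39 for Camp, 3.66 for S100a8, 3.91 for S100a9, -1.06 for Lta4h, 1.36 for Alox15, -0.95 for Ptgs1, -1.78 for Fkbp5 and -1.28 for Tsc22d3. Without the steep spleen libraries these were 2.21, 1.45, 0.86, 0.99, -0.94, 1.44, -0.83, -0.85 and -0.54, and of them Prtn3, Lta4h and Alox15 were called. After rest the difference was called for 529 genes, with 5.02 for S100a8 and 5.15 for S100a9, which were called at 4.22 and 4.30 without the steep libraries. Of 100 splits of the libraries, the real ones included, 1 gave as many genes as the 6249 after 10 defeats (highest other split 5586). After rest 3 gave as many as the 529 (highest other 793). These splits mixed stressed and control libraries within each tissue, which also removes a stress effect that both tissues share. They therefore cannot decide whether chance made the stress effects differ between tissues.

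In the next paragraphs the slope within cell type lists and the sums of pseudogenes and their parents were chosen before their results were seen; the other tests, splits included, were chosen after.

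In marrow after 10 defeats, B lineage genes fell and neutrophil genes rose while haemoglobin took a smaller share of the values. Where totals are equal, a smaller share raises every other gene by the same factor. Marrow totals averaged 998610 after 10 defeats and 964150 in controls. The 17 mature B cell genes with a mean of at least 5 had a median that differed by -2.75 from that of the other such genes (quartiles -2.85 and -1.58). A smaller share could not lower these genes, so this offset was no test of the share as the cause of the fall. The 22 such mature neutrophil genes lay 1.26 above the other genes (quartiles 0.96 and 1.39), which argues against the share as the whole cause of the rise. With the 12 haemoglobin genes taken out and totals made equal, 18 of 22 mature neutrophil genes were still higher, with a list median of 0.80 in place of 1.28. With equal totals the smaller share alone would raise the other genes by 0.44, but their median was -0.04. Median-ratio rescaling gave a list median of 1.42. The lower median of 0.80 therefore does not show that part of the rise follows the share. Each of 8 fits without 1 library left at least 21 mature B cell genes lower, which argues against a single library. A smaller share of B lineage cells alone is argued against by the 22 of 27 erythroid and 20 of 23 T cell genes that fell. Of 56 splits 1 gave as many as the 5694 genes called, the real one (highest other 2137), so chance is excluded at 0.05. Stress acting on the marrow stays open as an explanation, as does a change in the cells recovered from the femur, which was not tested.

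In spleen after 10 defeats, long genes fell together with lymphocyte genes while erythroid and early granule genes rose. The 4 steep libraries were chosen by their slope over all genes, and the same 5 spleen libraries are steep when the list genes are left out. A gene length trend is also seen within 13 cell type lists of 204 genes: the slope on log2 length in the 4 steep libraries minus that in the 2 flat ones was -0.42 (SE 0.0857), against -0.197 over 8608 genes. This SE treats the 204 genes as independent and does not measure variation between libraries. The trend is argued against as the whole cause, since 83 of 84 called members of the erythroid, early granule, T cell and mature B cell lists were still called with the length and GC trend taken out. Leaving out the steep libraries ended more of these calls, as given above, mainly in the mature B cell list and then in the erythroid list. The case is weaker for these lists, and weakest for the mature B cell list. A larger haemoglobin share moves every other gene of a library by the same factor, which is downward where totals are equal. Totals were not equal here, with means of 1485200 after 10 defeats and 811350 in controls. A common factor, up or down, leaves a list level with the other genes. The 45 T and mature B cell genes with a mean of at least 5 differed by -1.43 in their median from the other such genes (quartiles -2.03 and -1.01). This argues against the share as the whole cause of the lymphocyte part. RNA quality, which could bring such a trend, is not given in the sources used here. A response of the spleen to stress stays open for the cell type changes. Of 100 splits 2 gave at least as many genes as the 8196, the real one included, which excludes chance at 0.05; the other, with 9368 genes, set D6, D7, D9 and D10 against the controls with D4 and D5. It follows the steep length slopes and points to a structure of the samples.

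In spleen after 1 defeat, 96 genes passed the threshold with 2 libraries. With the length and GC trend of each library taken out, their median absolute fold change was 0.71 (median SE 0.233) in place of 1.21 (0.211), so 58.6% of it was left. Of the 96, 71 lost their calls because their changes shrank, from a median of 1.08 to 0.57, while the median SE went from 0.209 to 0.226. Settings that do not touch GC content also ended calls: median-ratio rescaling left 37, with a median of 1.12 (median SE 0.22) over the 90 of the 96 in that fit. A pseudocount of 0.1 left 27, with a median over the 96 of 1.92 and a wider spread (median SE 0.511). A GC and length trend and a response to 1 defeat cannot be told apart here, since both libraries of the group carry the trend and its removal took away only part of the change. Reads shared between a pseudogene and its parent gene could account for some of the pseudogenes. In 2 of 3 pairs the sum changed by under 0.5. The changes were -0.01 for Rpl17-ps5 with Rpl17, -0.27 for Rpl38-ps2 with Rpl38 and -0.52 for Ubb-ps with Ubb. The parents held most of each sum, averaging 2154, 1274 and 521 after 1 defeat against 6.94, 302 and 165 for the pseudogenes. A rise of a pseudogene alone could therefore leave its sum changed by under 0.5 too, so the sums cannot decide this.

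For the other comparisons with at least 3 libraries in both groups, splits gave these results. None were run in spleen for 1 or 4 defeats against controls or for 10 defeats against 1, where a group held 2 libraries. In marrow, 5 of 35 splits gave as many genes as the 1 called after 1 defeat (highest other 2), so chance is not excluded. After rest against controls 0 were called (limma; 1768 at an unadjusted p under 0.05), so each of the 35 splits gives as many (highest other 3) and they decide nothing. For 4 defeats against controls there are 10 splits, too few for a share under 0.05; the real one gave 2493 genes and the highest other 0. Chance is excluded at 0.05 for 10 defeats against 1 defeat in marrow (1 of 100 splits; 4838 genes, highest other 3954), for rest against 10 defeats in marrow (1 of 100; 2700, highest other 917) and for rest against controls in spleen (1 of 35; 1012, highest other 1). It is not excluded for rest against 10 defeats in spleen (7 of 100; 79, highest other 7390), where the highest split set D6, D9, D10 and rested library D2 against the others, again a structure of the samples.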

How the results depend on the processing

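Of 4160 alternative values of the 236 named gene results, 3912 kept their side of the threshold, 216 were no longer past it and 32 came to pass it. No value past it in either setting changed sign; 21 values of 6 genes, past it in neither, did. Counts below are genes called, marrow (M) or spleen (S), with the numbers of defeats compared (C, controls; R, rest); the cause was not tested unless given. Rescaling to equal totals, median-ratio rescaling, trend removal, library weights and leaving out steep libraries were chosen after seeing the data. Of the counts run under a setting, those not named with it stayed within 1.5 times the reported one.

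A log2 fold of at least 1, a stricter threshold by construction, left M 4-C 499, 10-C 965, 10-1 628, R-10 354 and S 10-C 4020, R-C 625, 10-1 4773, R-10 40. Quantile normalization gave M 1-C 0, R-C 71, S 1-C 319, R-10 47 and, between tissues after rest, 940. No filter gave M 1-C 4, R-C 5, S 1-C 423, R-10 22. A pseudocount of 0.1 gave M 1-C 0, S 1-C 27, 4-C 10, R-10 5. Rescaling to equal totals gave M 4-C 1115, 10-1 3130, S 4-C 24, R-C 443, R-10 5 and between tissues after rest 272. Median-ratio rescaling gave M 1-C 0, S 1-C 37, 4-C 0, R-10 35. The length trend removed gave M 1-C 0, S 4-C 3, and length with GC M 1-C 0, R-C 1, S 1-C 28, 4-C 13. Library weights gave M 4-C 4789, R-C 2531, R-10 4800, S 1-C 2512, 4-C 332, R-C 4427, R-10 8362. Only the groups compared gave M 1-C 0, R-C 396, S 1-C 1751, 4-C 22, R-10 0, and only control and stressed groups 805 between tissues after rest. Without the 5 steep libraries S 1-C was 1753, 4-C 245, 10-C 3243, of which 2878 were among the 8196, R-C 2260, R-10 5, and between tissues after rest 1315.

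Leaving out each replicate gave M 1-C 0 to 2, 4-C 684 to 3057, 10-C 3780 to 5780, R-C 0 to 0, 10-1 3553 to 5560, R-10 1301 to 3178; S 1-C 56 to 325, 4-C 2 to 195, 10-C 6567 to 9030, R-C 201 to 1099, 10-1 3731 to 8353, R-10 2 to 2316; between tissues 5277 to 7446 after 10 defeats and 156 to 851 after rest. Beyond the libraries named in the report, the count between tissues after rest was 259 and 189 without marrow C2 and C4, 242 and 295 without marrow D1 and D2, 299, 222, 843 and 210 without spleen C1, C2, C3 and C4, and 219 without spleen D2. In spleen after 1 or 4 defeats this leaves 1 library, assumed to vary like the other groups.

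With the shared number as a replicate block, the counts between tissues were 7088 after 10 defeats and 844 after rest. Same-numbered marrow and spleen libraries had correlations of -0.229 to 0.401 over 15 pairs, 7 above 0.1, and 8 correlated best with their own number. The number of best matches that chance would give was not computed. Where a spleen group held 2 libraries, the own and other correlations are opposite by construction (0.0587 and -0.0587 for D16). Shared animals are therefore not excluded, and the interaction test without the block treated such libraries as independent. The tests meant for read counts, with another normalization and another count test, were not run, since the values are scaled abundances. The depth of spleen library D16, the lowest estimated, limits what can be read from low genes after 1 defeat.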

Other observations

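Some stromal, clock and cholesterol genes were called in marrow beside the blood cell lists. After 10 defeats the called shares of these lists were close to the 5694 of 12442 genes called in all. After 10 defeats 7 of 16 stromal and 11 of 15 endothelial genes fell, and with quantile normalization 4 and 5 fell and 2 and 1 rose. The niche chemokine Cxcl12 (chromosome 6, 117168535 to 117181367) averaged 86.8 ± 20.6 in controls (SD, n = 3), 28.0 ± 7.47 after 10 defeats (SD, n = 5) and 118 ± 40.2 after rest (SD, n = 4), and the adipokine gene Adipoq changed by -1.63 ± 0.37 after 10 defeats. Against 10 defeats, rest brought rises of 2.02 ± 0.42 for Cxcl12, 1.47 ± 0.34 for Adipoq and 1.35 ± 0.18 for Lepr, in 7 of 16 stromal genes. The clock gene Arntl changed by -1.32 ± 0.23 and the clock output gene Nfil3 by 1.21 ± 0.19 after 10 defeats, and by 1.04 ± 0.21 and -0.80 ± 0.18 from there to rest. Of 15 clock genes 6 fell and 1 rose after 10 defeats, but 2 and 4 with quantile normalization. Cholesterol synthesis genes rose in 8 of 19 cases after 10 defeats (Msmo1 1.17 ± 0.24, Hmgcs1 0.68 ± 0.20; 7 adjusted over the list alone), and 4 fell from 10 defeats to rest. With quantile normalization these counts were 11 and 8 and with totals made equal 5 and 2. With an estimated correlation camera gave adjusted p = 0.732, 0.725 and 0.635 for the stromal, clock and cholesterol lists after 10 defeats. The hour at which tissue was taken is not given in the sources used here.

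In spleen after 10 defeats the basophil proteases Prss34 and Mcpt8 rose by 2.60 ± 0.31 and 3.07 ± 0.48, and 9 of 18 eosinophil, basophil and mast cell genes rose and 1 fell (5 and 0 without the steep libraries; camera adjusted p = 0.44 with an estimated correlation). The platelet chemokine Pf4 rose by 2.15 ± 0.47, without a call at 1.27 when the steep libraries were left out. Of 16 clock genes 14 fell, with Nr1d1 at -1.92 ± 0.41 and Arntl at -1.27 ± 0.25, but 7 fell with quantile normalization and 2 without the steep libraries (adjusted p = 0.719 with an estimated correlation over all libraries). Without the steep libraries Nr1d1, Arntl and Mcpt8 were at -0.91, -0.53 and 1.84 and called. Of 10 cytochrome P450 and epoxide genes 8 fell, 4 without the steep libraries.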
